A study of Physcomitrium patens with 10 samples.

How the data were processed

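Gametophores of Physcomitrium patens grown on BCD medium were sampled hydrated, at 2 degrees of dehydration and at 2 stages of rehydration. Per the labels' protocols, total RNA was extracted, fragments of 18 to 30 nt were enriched, adaptors were added at both ends, and the RNA was reverse transcribed and amplified by PCR before sequencing. Adaptor ligation and PCR copy some small RNAs better than others, so levels of different miRNAs in one state compare less well than the same miRNA between states. The aligner, the genome build, the miRNA reference and the way reads matching several family members were counted are not given in the sources used here. How the 2 replicates of a group were combined is not given either.

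Groups were taken from the sample titles, which give replicate numbers 2 and 3 for each of the 5 states. The treatment field disagrees with the title for 7 of the 10 samples and was not used. The file columns carry the group names of the titles and 1 value per group, so no column of a single library was used, and the replicate numbers could not enter any calculation.

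The 8 tables were of 2 kinds. The first kind holds levels in RPM (reads per 1000000) for hydrated gametophores and 1 other state, as deposited by the authors, with steps of 0.1 RPM. To which reads that total refers is not stated. The hydrated values are the same in all 4 such tables, so the states were joined through them. The second kind holds the authors' comparisons. Per the file headers these give a total and an expression value per group, here treated as a score, since the deposited total is 10000000 in every group and the expression value is 10 times the RPM. The true read totals and the depth of each library are therefore unknown, and no interval or floor was computed. The deposited log2 fold changes equal the log2 ratio of the RPM values with 0 replaced by 0.01, and the deposited p-value column gives the authors' p for each miRNA, whose test is not named in the headers. In the authors' deposited table a miRNA is marked where the fold change passes 2-fold and p is under 0.05, a rule that held for every mark.

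The designs written before the data were examined foresaw a count test or a linear model on libraries. Neither was used, because the values are single pooled values per group, for which those designs foresaw no test. Instead log2((RPM + 1)/(RPM + 1)) was computed, and miRNAs at least 2-fold higher or lower were counted among those with at least 30 on the deposited scale of 10 per RPM, which is 3 RPM, in the higher group. The pseudocount of 1 RPM understates the change of scarce miRNAs. The comparisons were MDH, SDH, PRE and FRE against HD, and PRE and FRE against SDH. Named in the text are, per comparison, the 10 largest rises and the 10 largest falls among miRNAs with at least 100 on the deposited scale (10 RPM) in the higher group, the member of each fixed list with the largest change, and the 5 most abundant miRNAs of HD. Names with identical values count as 1 item. Families and other names singled out beyond this rule were chosen after their values were seen.

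The 8 lists by family number were fixed at the same time. Conserved land-plant families were miR156, miR160, miR166, miR167, miR171, miR319, miR390, miR395, miR408, miR477, miR529, miR535 and miR536, and the list outside them took every other family. The auxin-related list held miR160, miR167, miR390, miR393 and miR1219, the regulators of developmental transcription factors miR156, miR529, miR166, miR171, miR319, miR534 and miR538, the nutrient and copper list miR395, miR397, miR398, miR399, miR408 and miR827, the small RNA machinery list miR162, miR168, miR403, miR904 and miR1047, and the families linked to stress in flowering plants miR159, miR169, miR319, miR393, miR394, miR396, miR398 and miR408. The last list held star or less abundant arms. Each list's median log2 fold change was placed as a percentile among 10000 random lists of the same size, matched on 5 bins of mean level. This describes these values and is no test across replicates, and names with near-identical copies weigh more than once in it.

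Near-identical copies, whose levels lay within 5% or 0.5 RPM of each other in all groups, were counted once as an alternative. They hold 99 of the 280 names, and 213 values remain. Reads shared between such copies cannot be assigned to one of them, so single copies are uncertain. Other alternatives were a pseudocount of 0 or 10 RPM, a minimum of 10 or 100 on the deposited scale or of 30 RPM, median-of-ratios scaling, the authors' marks and 1 summed value per family. The median-of-ratios factors were 1.09 for HD, 0.851 for MDH, 1.11 for SDH, 1.00 for PRE and 0.998 for FRE. Names past 2-fold in all 4 states were set against 1000 simulations of unchanged states that share 1 control value, with the spread of each miRNA taken from the 4 other states.

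The procedure was tested on simulated data for MDH against HD with 60 miRNAs changed by a known fold. Of these 0% were counted at a planted 1.5-fold (202 miRNAs tested), 98.3% at 3-fold (200 tested) and 100% at 6-fold (204 tested), with 0 others counted. The simulation used a small assumed spread and none between pools or libraries, so it checks the arithmetic and says nothing about how often unchanged miRNAs would be counted. No genome of this moss was used, so no coordinates are given, and 0 of the miRNA names matched the table of gene names. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.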

Results

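Small RNAs were sequenced from gametophores, the leafy shoots, of the moss Physcomitrium patens in 5 states: hydrated (HD), moderately dehydrated (MDH), severely dehydrated or desiccated (SDH), partially recovered after rewetting (PRE) and fully recovered (FRE). By their titles the 10 samples form 5 groups of 2 replicates, though the treatment field disagrees with the title for 7 of them. The values analysed were 280 mature miRNA names from 108 family numbers, in RPM (reads per 1000000), with 1 authors' value per state. The replicates had already been combined, so no error, interval or p-value could be attached to a difference, no difference below has a replicate check, and the depth behind each value is unknown. A miRNA is called higher or lower where log2((RPM + 1)/(RPM + 1)) passed 2-fold, and printed folds are plain ratios of RPM. No ratio is given where either level lay under 1 RPM, since the pseudocount then sets the size of the log2 value.

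The miR535 family was the most abundant in every state. Its 4 names held 57.9% of the RPM summed over all names in HD, 45.1% in MDH, 46.8% in SDH, 44.7% in PRE and 55.3% in FRE. The miR156 family, which targets SPL transcription factors of shoot development, followed in HD with 15.9% and held 16.4%, 16.1%, 12.8% and 9.86% in MDH, SDH, PRE and FRE. Summed over all names, the level was 831487 RPM in HD, 503544 in MDH, 629248 in SDH, 407334 in PRE and 571803 in FRE. These sums count names of near-identical copies separately, and with 1 value per set of copies they were 450737, 286164, 350225, 226788 and 312265 RPM. Between 252 names (MDH) and 262 names (HD) lay above 0, and 13 names were listed at 0 in every state.

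**Figure D1:**
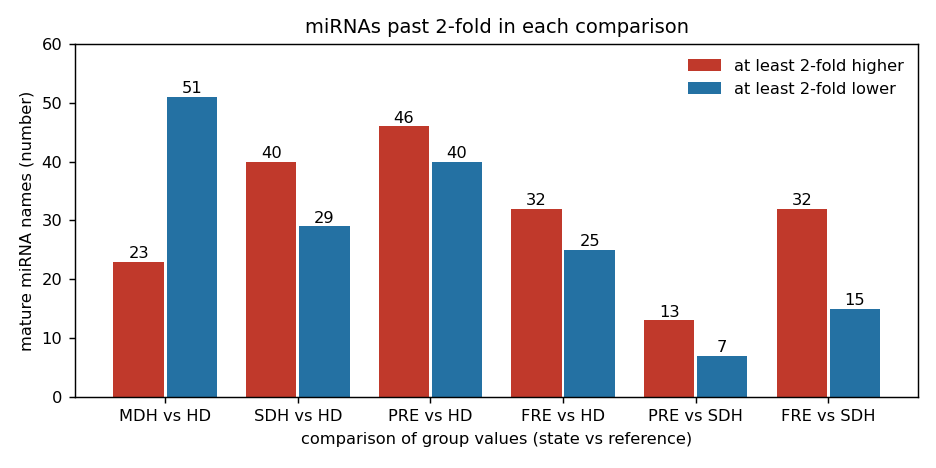
Numbers of mature miRNA names at least 2-fold higher (red) or lower (blue) in each of the 6 comparisons, from 1 value per group. MDH against HD had 23 higher and 51 lower, and PRE against HD had 46 and 40.

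The first comparison asked which miRNAs differed between moderately dehydrated and hydrated gametophores. The largest gain in level was that of miR1023a-3p, at 3805 RPM in HD and 45433 RPM in MDH, 11.9-fold higher, and its other arm miR1023a-5p was 13.9-fold higher, at 4.0 and 55.6 RPM. Its relative miR1023e-3p went the other way, at 1744 and 11.8 RPM, 148-fold lower. The copper-linked miR408b, whose family targets copper proteins, was at 114 RPM in HD and listed at 0 in MDH. Of 209 miRNAs above the minimum level, 23 were at least 2-fold higher and 51 at least 2-fold lower, in 9 and 28 families, and 10 and 27 of them passed 4-fold.

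Among the other higher miRNAs, miR477g-3p was at 697 RPM against 102 in HD (6.87-fold), and miR477f and miR477g-5p were both at 262 against 41.1 RPM. Of 10 miR477 names 5 were higher and none lower. miR1052 was at 2041 against 352 RPM (5.8-fold), miR2080 at 114 against 29.2 RPM (3.91-fold), and miR902i-5p and miR902h-5p were 4.7-fold and 4.59-fold higher. miR534a, which targets BLADE-ON-PETIOLE genes in this moss, was at 0.8 RPM in HD and 18.2 RPM in MDH. On the lower side stood miR1043-3p, at 859.5 RPM in HD and 6.9 in MDH (125-fold), and miR1073-3p at 745 and 15.1 RPM (49.3-fold), with its partner arm miR1073-5p at 24.2 and 0.2 RPM. The abundant miR1221-5p was at 17068 RPM in HD and 866 in MDH, 19.7-fold lower. miR1077-3p, miR1041 and miR1072 lay at 51.4, 43.3 and 37.6 RPM in HD and at 0.6, 0.8 and 0.8 RPM in MDH, and miR1023c-3p was 37.9-fold lower. All 8 names of miR1063 were lower, with a median log2 fold change of -2.04. Some of these names had the same fold changes in every comparison, such as miR1063b and miR1063h, so they are not 8 separate observations.

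By the fixed lists, 7 of 65 names of conserved land-plant families were higher (5 of miR477, and miR529e and miR529f) and 10 lower (among them the 4 miR535 names and miR408b). Their median log2 fold change was -0.37, at percentile 90.2 of random lists matched on level. Of 144 names from families outside that list 16 were higher and 41 lower, with a median of -0.52 at percentile 0.01. With 1 value per set of copies the medians of those 2 lists were -0.40 and -0.56. With members summed per family they were -0.55 and -0.49, so the order of the 2 lists depended on how names were counted. Random lists of 144 names take most of the 209 tested, so their medians lie close together and small differences give extreme percentiles. None of 16 auxin-related names was higher and 5 were lower (median -0.69, percentile 6.47): miR160b and miR160i, which target auxin response factors, miR1219d with the same kind of target in moss, and miR390c, whose mature strand starts the production of TAS3 small interfering RNAs, with its star arm. With median-of-ratios scaling the conserved names stood at 11 higher and 4 lower, and 3 auxin-related names were lower, without miR160b and miR160i. miR390c was at 179 against 985.5 RPM (5.49-fold lower). Of 36 regulators of developmental transcription factors 3 were higher (miR534a, miR529e and miR529f) and 1 was lower, miR529g (median -0.37, percentile 92.4).

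Of the 8 stress-linked names none was higher and 1, miR408b, was lower. The other 7 were of miR319, here, in the other comparisons with HD and in PRE against SDH. The list's median and percentile therefore describe mainly that 1 family. The 8 names had a median of 0.10 at percentile 95.9, while miR408b drew their mean to -0.79, and their median with members summed per family was -3.69. That mean and summed median both rest on miR408b at 0 RPM in MDH, so the pseudocount sets their size. miR408b was also the sole tested member of the nutrient and copper list. The 3 small RNA machinery names stayed under 2-fold (median 0.37, mean -0.07, percentile 71.9, and median -0.28 with members summed per family), and miR1047-3p among them was at 3.7 against 8.0 RPM, a log2 fold change of -0.94. Of 29 star or less abundant arms 6 were higher and 9 lower, with a median of -0.17 (0.14 with median-of-ratios scaling, -0.82 with members summed per family) at percentile 49.7. The most abundant names, miR535d and miR535a, were at 63177 against 129549 RPM and at 54655 against 117173 RPM, and miR156a was at 31565 against 47234 RPM, a log2 fold change of -0.58.

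Median-of-ratios scaling moved the median log2 fold change of all tested miRNAs by 0.35 in this comparison, and the split became 30 higher and 36 lower, so that 54.5% of the miRNAs past 2-fold were lower in place of 68.9%. The log2 fold changes of miR535d and miR535a, -1.04 and -1.10, became -0.68 and -0.75 and no longer passed 2-fold.

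Desiccated gametophores were then set against hydrated ones. miR1023a-3p stood at 38776 RPM, 10.2-fold above HD, and miR1023e-3p at 155 RPM, 11.2-fold below it. miR408b was at 0.1 RPM and miR1077-3p also at 0.1 RPM. The miR477 family was higher as a group, with 9 of 10 names past 2-fold, and 12 of 23 names of miR902 were higher with none lower. The miR902 calls came from scarcer members, and the family summed to 6181 RPM in HD and 5729 RPM in SDH, a log2 fold change of -0.11. Of 215 miRNAs tested, 40 were higher and 29 lower, in 13 and 17 families.

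Within these groups, miR477g-5p was at 266 RPM (6.46-fold above HD), miR477f at 265 RPM and miR477g-3p at 626 RPM (6.17-fold). miR902h-3p was at 82.1 against 17.7 RPM (4.64-fold), miR902j-5p at 115 against 25.1 RPM (4.57-fold), and miR902i-5p at 27.4 RPM. miR1052 was at 1794 RPM, 5.1-fold above HD, miR1023a-5p at 40.6 RPM and miR534a at 12.5 RPM. Of 10 miR1223 names 8 were higher and none was lower, while the family summed to 479 RPM in HD and 805 RPM in SDH, a log2 fold change of 0.75. Lower were miR1043-3p at 18.4 RPM (46.7-fold), miR1073-3p at 55.6 RPM (13.4-fold), miR1073-5p at 0.5 RPM, miR1072 at 2.4 RPM (15.7-fold) and miR1023c-3p at 2.9 RPM (14.4-fold). miR2083-3p was at 3.7 against 28.0 RPM (7.57-fold), miR1041 at 6.4 RPM (6.77-fold), and all 8 miR1063 names were lower again, with a median log2 fold change of -1.39.

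Of 65 conserved names 9 were higher, all of miR477, and 4 were lower: miR408b, miR390c, its star arm and miR529g (median -0.17, percentile 53.9). With 1 value per set of copies 5 were higher and 4 lower. The star arm of miR390c was at 7.7 against 30.1 RPM (3.91-fold lower), and no other of the 16 auxin-related names passed 2-fold than miR390c and this arm (median 0.01, mean -0.23, percentile 12.6; the median was -0.01 with median-of-ratios scaling). Of 36 developmental regulators miR534a was higher and miR529g lower (median -0.18, percentile 40.6). Of 150 names outside the conserved list 31 were higher and 25 lower (median 0.11, mean -0.04, percentile 70.3), and of 30 star or less abundant arms 10 and 6 (median 0.14, mean -0.01, percentile 45.1, and median -0.53 with members summed per family). miR408b was lower in the stress-linked list of 8 (median -0.43, mean -1.24, percentile 11.9, and median -3.70 with members summed per family) and alone in the nutrient and copper list. With miR408b at 0.1 RPM the pseudocount sets the size of that mean and summed median. The 3 machinery names stayed under 2-fold (median 0.51, percentile 77.1), with miR904b, which targets the AGO1 gene in moss, at 1043 against 731 RPM. miR535d was at 79535 RPM and miR156a at 37437 RPM, log2 fold changes of -0.70 and -0.34.

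The direction of the split depended on the low levels. With a pseudocount of 10 RPM it was 21 higher and 26 lower, and with a minimum of 30 RPM it was 20 and 25.

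**Figure D2:**
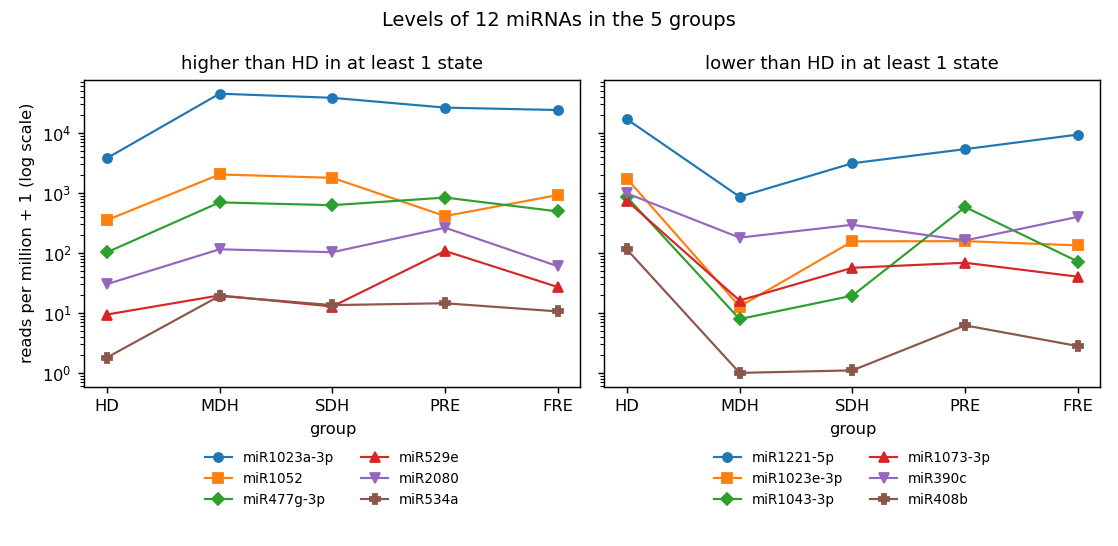
Levels of 12 miRNAs in the 5 groups as RPM + 1 on a log axis, 1 value per group joined by lines, with miRNAs higher than HD in at least 1 state on the left and lower on the right. miR1023a-3p lay above its HD level of 3805 RPM in all 4 other states, and miR408b below its HD level of 114 RPM.

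Partially rehydrated gametophores were compared with hydrated ones to ask how far miRNA levels still differed at partial rehydration. Here miR529e and miR529f, which target SPL genes like miR156, had the largest log2 fold changes upward of the named miRNAs (3.52 for both), at 107 against 8.4 RPM. They were scarce members: the miR529 family summed to 5811 RPM in HD and 5256 RPM in PRE, a log2 fold change of -0.14, and 2 of its 7 names were lower. The most abundant families, miR535 and miR156, were lower: all 4 miR535 names, with miR535d at 48898 RPM (2.65-fold), and all 3 miR156 names, with miR156a at 19250 RPM (2.45-fold). miR904b was at 1723 RPM, 2.36-fold above HD, and all 4 names of miR537 were higher, with a median log2 fold change of 1.09. Of 213 miRNAs tested, 46 were higher and 40 lower, in 16 and 20 families.

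Higher too were miR2080 at 263 RPM (9.01-fold), miR477g-5p at 353 RPM (8.6-fold), miR477f at 353 RPM, miR477g-3p at 839.6 RPM (8.27-fold) and miR1023a-3p at 26612 RPM (6.99-fold). miR902l-3p was at 23.8 against 2.1 RPM (11.3-fold), miR1076-5p at 16.8 against 1.4 RPM, and miR534a at 13.5 RPM. Among the lower miRNAs, miR1072 was at 1.2 RPM (31.3-fold), miR1077-3p at 1.7 RPM (30.2-fold), miR1041 at 1.7 RPM (25.5-fold) and miR408b at 5.2 RPM (21.9-fold). miR1023e-3p, miR1073-3p and miR1023c-3p were at 157, 67.7 and 3.8 RPM. All 4 miR390 names were lower, with miR390c at 161 RPM (6.12-fold) and its star arm at 8.6 RPM (3.5-fold), and miR900-3p was at 16.8 against 55.9 RPM (3.33-fold).

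Of 65 conserved names 12 were higher, with 9 of miR477 and miR529e, miR529f and miR536f, and 18 were lower (median -0.49, percentile 29.9). With 1 value per set of copies 7 were higher and 13 lower. Of 36 developmental regulators 3 were higher, miR534a, miR529e and miR529f, and 9 lower, among them 3 each of miR156 and of miR166, whose targets are HD-ZIP III genes (median -0.50, percentile 72.0). The 4 lower of the 16 auxin-related names were those of miR390 (median -0.03, 0.07 with median-of-ratios scaling; percentile 12.3). Both miR904 names, which are near-identical copies, were higher in the machinery list of 3 (median 1.23, percentile 88.55). With 1 value per set of copies its median was 0.63. The stress-linked list had 2 of 8 lower, miR408b and miR319d.2* at 3572 against 10045 RPM (median -0.26, mean -0.92, percentile 46.2, and median -2.81 with members summed per family), and miR408b, at a log2 fold change of -4.21, was the nutrient and copper list. Outside the conserved list 34 of 148 names were higher and 22 lower (median -0.01, 0.10 with median-of-ratios scaling; percentile 68.9), and of 29 star or less abundant arms 7 and 5 (median -0.17, mean 0.16, percentile 10.6).

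With 1 value per set of near-identical copies the split was 27 higher and 30 lower, and with a pseudocount of 10 RPM or a minimum of 30 RPM it was 25 and 34 or 24 and 38. Median-of-ratios scaling moved the median of all tested miRNAs by 0.10 and gave 48 higher and 33 lower.

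In fully rehydrated gametophores against hydrated ones, several names that led the earlier comparisons stood apart again. miR1023a-5p was at 53.5 RPM (13.4-fold above HD) and miR1023a-3p at 24258 RPM (6.38-fold), while miR408b was at 1.8 RPM (63.2-fold below HD), miR1073-3p at 39.2 RPM (19-fold) and miR1023e-3p at 133 RPM (13.1-fold). All 3 miR156 names were lower, with miR156a at 21727 RPM (2.17-fold), a log2 fold change of -1.12 that came just short of 2-fold with median-of-ratios scaling. Of 209 miRNAs tested, 32 were higher and 25 lower, in 12 and 16 families.

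Of 22 miR902 names 11 were higher and none lower, while the family sum of 6073 RPM lay close to HD (log2 fold change -0.03). Among the higher were miR902l-3p at 15.7 RPM (7.48-fold), miR902i-5p at 26.0 RPM (3.88-fold) and miR902h-5p at 26.3 RPM (3.81-fold). miR477g-3p was at 493 RPM (4.85-fold), miR477g-5p and miR477f at 195 RPM, miR529e and miR529f at 26.0 RPM (3.1-fold) and miR534a at 9.6 RPM. Lower were miR1043-3p at 70.9 RPM (12.1-fold), miR1073-5p at 1.2 RPM (20.2-fold), miR1072 at 6.5 RPM (5.78-fold), miR1023c-3p at 3.6 RPM, miR529g at 8.3 against 41.3 RPM (4.98-fold), miR2083-3p at 7.5 RPM (3.73-fold) and miR1077-5p at 16.0 against 54.7 RPM (3.42-fold).

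Of 65 conserved names 6 were higher and 9 lower (median -0.22, percentile 47.1). In the auxin-related list of 16, miR1219a, miR1219b and miR1219c were higher and miR390a, miR390b and miR390c lower, with miR390b at 462 against 1171 RPM (2.54-fold). The 3 miR1219 names have identical values, and with 1 value per set of copies 1 was higher and 3 lower. By name the list median was 0.08 (mean -0.01, percentile 29.8). Of 36 developmental regulators 3 were higher and 5 lower, the latter from miR156 and miR529 (median -0.37, percentile 26.0). miR408b was the lower 1 of 8 stress-linked names, the other 7 being of miR319. That list had a median of 0.51 (mean -0.26, percentile 98.1, and median -2.42 with members summed per family). miR408b stood alone for nutrients and copper (-5.36). The 3 machinery names stayed under 2-fold (median 0.18, percentile 72.0, and median -0.04 with 1 value per set of copies), with miR1047-3p at 6.5 RPM. Outside the conserved list 26 of 144 were higher and 16 lower (median -0.09, 0.02 with median-of-ratios scaling; percentile 35.4), and of 29 star or less abundant arms 10 and 5 (median -0.09, mean 0.21, and 0.02 with that scaling; percentile 16.3). miR535d, at 84852 RPM, had a log2 fold change of -0.61.

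With a pseudocount of 10 RPM the counts were 11 higher and 22 lower, with a minimum of 30 RPM 11 and 21, and with 1 value per set of copies 21 and 24. Median-of-ratios scaling moved the median of all tested miRNAs by 0.12.

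Over the 4 states, 13 names were at least 2-fold higher and 11 at least 2-fold lower than HD in every state. Higher throughout were both arms of miR1023a, miR534a, miR477f, miR477g-3p, miR477h, miR1076-5p, miR902h-5p, miR902j-5p and miR1223f with their near-identical copies. Lower throughout were miR408b, miR1023c-3p, miR1023e-3p, both arms of miR1073, miR1072, miR1077-3p, miR390c, miR529g, miR1039-3p and miR1042-3p. Counted once per set of copies these were 10 and 11 of 151. The 4 comparisons share the HD value: simulated unchanged states against a shared control gave 2.24 and 2.12 on average and at most 8 in 1000 simulations, and independent lists would share 0.0909 and 0.193. The simulations drew each miRNA separately and gave HD the spread of the 4 other states. They leave out an HD pool that differs as a whole, so the highest simulated count is no bound for the 10 and 11. With 1 HD value the controls cannot be split into separate sets, so part of the excess over independent lists may come from sharing them.

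**Figure D3:**
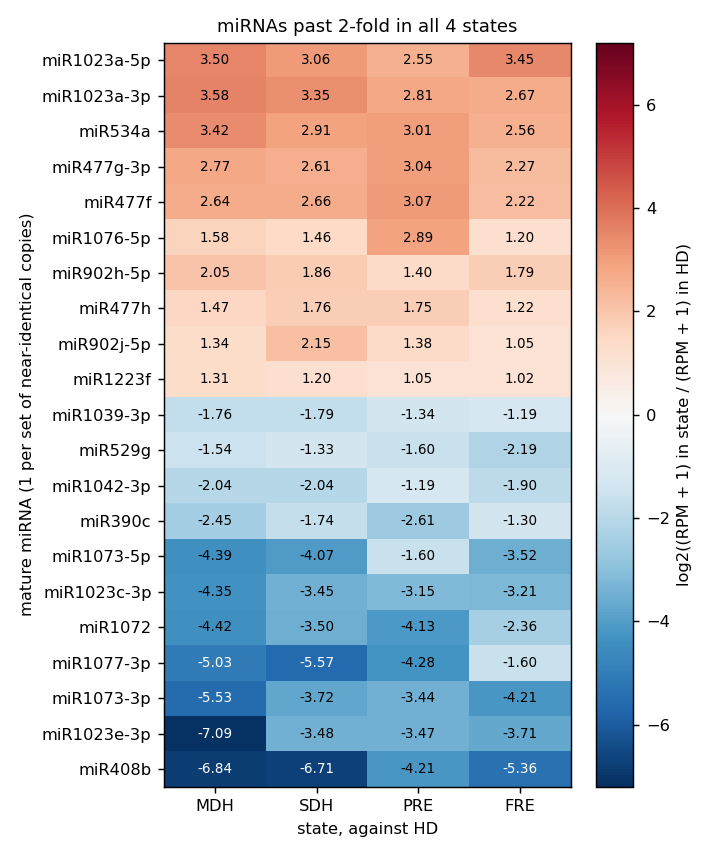
Log2((RPM + 1)/(RPM + 1)) of each state (columns) over HD for the 21 sets of miRNAs past 2-fold in all 4 states (rows, 1 name per set), red where higher and blue where lower. miR1023a-3p runs from 3.58 in MDH to 2.67 in FRE, and miR1073-3p from -5.53 to -4.21; where a level lay under 1 RPM, as for miR408b in MDH and SDH, the pseudocount sets the size.

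The rehydrated states were also set against the desiccated state, with levels joined across tables that give the same HD values. In PRE, miR1043-3p was at 583 RPM against 18.4 in SDH, 31.7-fold higher, and miR529e at 107 against 11.8 RPM, 9.08-fold higher, with miR529f alike. miR903 was at 597 against 93.6 RPM (6.38-fold) and miR2083-3p at 24.6 against 3.7 RPM (6.65-fold). On the other side miR1052 was at 412 against 1794 RPM (4.35-fold lower) and miR1050 at 355.5 against 1098 RPM (3.09-fold lower). Few miRNAs passed 2-fold, 13 higher and 7 lower of 211.

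Other higher miRNAs were miR1221-3p at 195 against 71.5 RPM (2.72-fold), miR2080 at 263 against 102 RPM (2.58-fold), miR1076-5p at 16.8 against 5.6 RPM and miR902l-3p at 23.8 against 9.1 RPM. miR408b was at 5.2 against 0.1 RPM and miR1073-5p at 7.3 against 0.5 RPM. Other lower miRNAs were miR902h-3p at 30.0 against 82.1 RPM (2.74-fold), miR390b at 509 against 1217 RPM (2.39-fold), miR390a alike, and miR900-3p at 16.8 against 38.3 RPM. miR1026b (log2 fold change 0.87), miR166j (-0.99), miR533a* (-0.98), miR156a (-0.96), miR535d (-0.70) and miR904b (0.72) stayed under 2-fold, though miR1026b passed it with median-of-ratios scaling (1.01).

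Of 65 conserved names 3 were higher and 2 lower (median -0.32, percentile 33.4), of 16 auxin-related names 0 and 2 (median -0.03, 0.10 with median-of-ratios scaling; percentile 61.7), and of 36 developmental regulators 2 and 0, miR529e and miR529f (median -0.32, percentile 65.4). The machinery list had none of 3 past 2-fold (median 0.72, mean 0.39, percentile 98.1). Its 2 miR904 names are near-identical copies that set this median, and with 1 value per set of copies it was 0.22. miR408b was the higher 1 of 8 stress-linked names (median 0.16, percentile 83.6, and median 0.89 with members summed per family) and the sole tested name of the nutrient and copper list. Outside the conserved list 10 of 146 were higher and 5 lower (median -0.15, mean 0.02, percentile 55.3), and of 29 star or less abundant arms 6 and 1 (median -0.19, mean 0.14, percentile 23.2). Median-of-ratios scaling moved the median of all tested miRNAs by 0.14 and gave 15 higher and 7 lower. The 20 miRNAs past 2-fold became 12 with a pseudocount of 10 RPM (7 higher, 5 lower) and also 12 with a minimum of 30 RPM (6 and 6).

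In FRE against SDH the abundant miR1221-5p was at 9448 against 3138 RPM, 3.01-fold higher, and miR319d.2* at 14558 against 6112 RPM, 2.38-fold higher. miR1077-3p was at 16.3 against 0.1 RPM, miR1041 at 30.9 against 6.4 RPM (4.83-fold) and miR1043-3p at 70.9 against 18.4 RPM (3.85-fold). All 4 miR1219 names were higher, with miR1219a at 21.1 against 6.1 RPM (3.46-fold) and miR1219d at 22.7 against 6.6 RPM. Lower were miR1050 at 278 against 1098 RPM (3.95-fold), miR1065 at 117 against 331 RPM (2.83-fold) and miR390b at 462 against 1217 RPM (2.64-fold). Of 214 miRNAs 32 were higher and 15 lower.

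Further higher miRNAs were miR903 at 258 RPM (2.75-fold), miR1221-3p at 196 RPM and miR1218 at 65.5 against 25.7 RPM (2.55-fold). miR390a, miR1077-5p, miR902j-5p at 53.1 against 115 RPM (2.16-fold), miR1023b-3p at 188 against 401 RPM (2.14-fold), miR1223b and miR1223c, and miR1216 at 12.7 against 27.8 RPM were lower. Of the 5 most abundant names of HD none passed 2-fold, with log2 fold changes of 0.09 for miR535d and -0.78 for miR156a, while miR156b, chosen after its value was seen, was at 12903 against 26391 RPM (2.05-fold lower). With median-of-ratios scaling miR156b, miR1077-5p, miR902j-5p, miR1023b-3p, miR1223b, miR1223c and miR1216 no longer passed 2-fold, at log2 fold changes of -0.97 to -0.88.

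All 7 stress-linked names tested were of miR319, which targets TCP and MYB genes, so the list stood for 1 family here. Of these names 4 were higher (median 1.02, percentile 97.7). Of 16 auxin-related names 5 were higher, the 4 of miR1219 and the star arm of miR390c, and miR390a and miR390b were lower (median -0.19, mean 0.22, percentile 29.8). With 1 value per set of copies 3 were higher and 2 lower. Of 36 developmental regulators 6 were higher and 1 lower (median -0.19, percentile 51.1), and of 64 conserved names 7 and 3 (median -0.22, percentile 19.5). The lower developmental regulator was miR156b, and with median-of-ratios scaling these lists had 8 and 0 and 9 and 2, while outside the conserved list 25 were higher and 4 lower. Outside the conserved list 25 of 150 were higher and 12 lower (median -0.07, 0.07 with median-of-ratios scaling, mean 0.04, percentile 99.6). With 1 value per set of copies its median was -0.18 and with members summed per family -0.15, where that of all tested names was -0.19. The list holds 150 of the 214 names tested, so small differences give extreme percentiles. Of 29 star or less abundant arms 5 were higher and 1 lower (median 0.10, percentile 93.9), none of the 3 machinery names passed 2-fold (median -0.33, percentile 44.7), with miR1047-3p at a log2 fold change of -0.57, and no nutrient and copper name reached the minimum level. Median-of-ratios scaling moved the median of all tested miRNAs by 0.15 and gave 34 higher and 6 lower, so that 15.0% of the miRNAs past 2-fold were lower in place of 31.9%. The 47 miRNAs past 2-fold became 16 with a pseudocount of 10 RPM and 29 with a minimum of 30 RPM.

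Of 8 sets of copies at least 4-fold above HD in SDH, 2 lay within 2-fold of HD in PRE, those of miR1052 and miR902h-3p, and none did in FRE. Of 12 sets at least 4-fold below HD in SDH, miR1043-3p and miR2083-3p lay within 2-fold in PRE, and miR1041 and miR1221-5p did in FRE. Their median log2 fold change against HD was -3.49 in SDH, -3.30 in PRE and -2.79 in FRE, and that of the 8 higher sets was 2.64, 2.68 and 2.24. Both groups of sets were chosen by their SDH values, which alone can place the PRE and FRE values closer to HD. All states were also compared with the same HD value, and an extreme HD value keeps a set off HD in every state. The counts and medians therefore cannot tell a return or a lasting change from these effects.

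The authors' deposited table for MDH against HD marked 83 miRNAs of 235 listed, 23 higher and 60 lower. For SDH the authors' deposited table marked 47 higher and 32 lower, for PRE 54 and 44, and for FRE 36 and 27. Every miRNA past 2-fold here against HD was among those marked in the authors' deposited table, which marked 9, 10, 12 and 6 more in the 4 states. Both rest on the same RPM values, and the pseudocount only shrinks a change, so this overlap is no independent support.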

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

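The counts with 1 value per set of near-identical copies and with a minimum of 30 RPM were chosen after the data were seen. No paired analysis was possible because the columns carry 1 value per group and no replicate numbers. For the same reason leaving out a replicate, the count tests and linear models on libraries, fits of only the compared groups, no low-count filter in such fits, and grouping by the treatment field were not run. Leaving the most abundant miRNA out of the library totals was not run, since those totals are not known. The number of miRNAs past 2-fold lay within 1.5 times the main number in all 6 comparisons with median-of-ratios scaling, a pseudocount of 0 and a minimum of 10 or 100 on the deposited scale. It also did in all 4 against HD with the authors' marks from the authors' deposited table, which rest on the same RPM values. With a minimum of 30 RPM, which tests fewer miRNAs, it was 45 for SDH (main 69), 32 for FRE (57), 12 for PRE against SDH (20) and 29 for FRE against SDH (47). With a pseudocount of 10 RPM, which shrinks the change of scarce miRNAs, it was 33 for FRE, 12 for PRE against SDH and 16 for FRE against SDH. With 1 value per set of copies, which tests fewer values, it was 57 for PRE (86). Median-of-ratios scaling moved no list median by more than the limit of 1.5-fold. It could not have done so, because it shifts all miRNAs of a comparison nearly alike. The median of all tested miRNAs moved by at most 0.35 in log2 with it, which is under 1.5-fold. With members summed per family 8 of 47 list medians moved past the limit. The stress-linked median was then -3.69 for MDH, -3.70 for SDH, -2.81 for PRE, -2.42 for FRE and 0.89 for PRE against SDH, where 2 families, miR319 and miR408, are left to make it. In comparisons with MDH or SDH, where miR408 lay under 1 RPM, the pseudocount sets its size. The small RNA machinery median for MDH was -0.28, the midpoint of miR904 (0.37) and miR1047 (-0.94). By name the 2 near-identical copies of miR904 outweigh miR1047-3p. The median of star or less abundant arms was -0.82 for MDH and -0.53 for SDH, and the cause of this move was not tested. Of the named miRNAs, 21 of 160 moved past that limit with a pseudocount of 0 and 56 of 161 with a pseudocount of 10 RPM. With median-of-ratios scaling 0 of 161 moved past it, which the small size of that shift fixed in advance. None past 2-fold changed sign. Unknown depth limits all of this: whether differences among miRNAs of a few RPM exceed counting noise is not known.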

Other observations

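The tests on miR1023 were chosen after the result was seen, and so were the families described first.

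miR1026a was at 749.8 RPM in HD, 114 in MDH, 338 in SDH, 617 in PRE and 757 in FRE, so that it lay more than 2-fold below HD in both dehydrated states and within 2-fold of it in PRE and FRE. miR1063a was likewise lowest in MDH, followed by SDH, PRE and FRE, at 226 RPM in HD and 53.5, 89.9, 108 and 153 RPM in the 4 other states. miR903 was at 104 RPM in HD, 93.6 in SDH and 597 in PRE. In the miR390 family the members differed: miR390a was at 1232 RPM in HD and 1253 in SDH but 525 in PRE and 492 in FRE, while miR390c was at 985.5, 294, 161 and 400 RPM.

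HD was the lowest of the 5 groups for 39 of 151 sets of copies (25.8%) and the highest for 53 (35.1%), where chance gives 20%. With 1 value per group, a hydrated pool that differs from the others as a whole is not excluded.

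More miRNAs were at least 2-fold lower than higher in MDH against HD. Counting near-identical copies more than once does not account for it, since with 1 value per set 68.3% of the values past 2-fold were still lower. With median-of-ratios scaling 54.5% were lower. That scaling need not even a split, as that of FRE against SDH became less even with it. It brings the median near 0 whatever the source of the shift, which leaves open whether library composition contributed. A change in the state of the tissue stays open and untested.

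miR1023a-3p was higher, and miR1023c-3p and miR1023e-3p lower, than HD in all 4 states. Reads moved from other family members by mapping are argued against as the whole source of the gain. The gain of miR1023a-3p was at least 11.5 times the net summed loss of miR1023b-3p, miR1023c-3p and miR1023e-3p in every state. That loss is net because miR1023b-3p lay above HD in SDH, at a log2 fold change of 0.31. In MDH the gain was 41628 RPM and the loss 2011 RPM. A larger amount of the miR1023a precursor is a candidate explanation for the gain, since the other arm was at least 7.05-fold above HD in every state. Its transcription was not measured in the values used here. For the loss, mapping stays open: it amounted to at most 8.72% of the gain, so all of it fits inside that gain.

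The arms of most hairpins shifted in the same direction against HD, in 17 of 23 hairpins in MDH, 21 of 24 in SDH, 16 of 23 in PRE and 18 of 23 in FRE. Across hairpins, which are not independent replicates, the log2 fold changes of the arms correlated with Pearson's r of 0.852 in MDH (Spearman's rho 0.799), 0.743 in SDH (rho 0.781), 0.709 in PRE (rho 0.688) and 0.844 in FRE (rho 0.694). Permutation p of r was 0.0001 in MDH and FRE, the smallest that 10000 permutations can give, 0.0003 in SDH and 0.0004 in PRE, and Benjamini-Hochberg values over the 4 states were at most 0.0004. Near-identical copies, such as miR902a-3p and miR902b-3p (both -0.77 in MDH), entered as separate hairpins, so these p-values may be too small. The 4 states also share the HD value, so they are not 4 separate tests. The 2 farthest hairpins do not carry the correlation alone, since without them r was still at least 0.609. Other hairpins with large shifts stayed in, such as miR1221 in MDH (-4.30 and -3.74). Whether a larger set of such hairpins carries the correlation was not tested. The lowest r was 0.709, and changes in precursor amount may contribute for many hairpins but are not shown for each: the arms of miR1076 stood at -0.72 and 2.89 in PRE and those of miR902k at -1.20 and 0.54 in MDH, and with no replicate spread these exceptions cannot be weighed.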
